A study of Mus musculus with 64 samples.

How the data were processed

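RNA was extracted with Trizol and RNeasy columns and libraries were made with an Illumina kit, per the labels. The deposited tables cover 64 libraries in 4 tissues, and the groups follow the labels. The authors' notes name STAR 2.7.8a, Partek and the builds mm10 and GRCm39 without stating the role of each. That the replicates of a group are separate animals is taken from the labels alone, so the p-values measure the spread between these samples.

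The labels call all values CPM, which the values contradict. In the deposited liver and heart tables the unit is a scaled signal: estimated reads per gene divided by 1 factor per library. The columns sum to 14840727 to 18537114, and 80.9 to 83.7 percent of the values between 0.05 and 100 are whole multiples of a step specific to each library, within 0.02 reads. The deposited lung and fat tables hold expected counts, estimated reads per transcript that were not scaled between libraries. Their transcripts were summed per gene symbol and rounded. Liver and heart depth was estimated from the step of each library.

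Before the data were examined, the groups, the comparisons, the tests, the gene lists, the rule for naming genes and a first set of alternatives were fixed. In each tissue 1 model with a mean per group gave 5 comparisons, 20 in all: training in vehicle mice, training in knockout mice, knockout in sedentary mice, knockout in trained mice, and the difference between the training effects. For liver and heart the values were divided by 1 factor for the whole tissue, which brings the mean library to the scale of CPM, genes with a mean of at least 1 were kept, and limma 3.58.1 with a trend was run on log2 of the value plus 1. For fat and lung, edgeR 4.0.16 was run with TMM factors, its filter by group and its quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes under 0.05 are called. The SE of an edgeR fold change is its size divided by the square root of its F statistic. Programs ran in R 4.3.3.

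Gene lists, 40 in number, were tested with limma's camera at a preset correlation of 0.01, and adjusted over the lists and comparisons of a tissue. Of 500 such tests 144 passed. With a correlation estimated from the data 0 of the 144 passed, and with limma's rotation test fry 0 passed.

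Genes were named by rank: per comparison, those with the largest rises and falls among called genes at 2 CPM or more (8 each way for training in vehicle and knockout in sedentary mice, otherwise 5), up to 4 called members of each list, and the 4 smallest p-values where none was called. Predicted genes, clone names, pseudogenes and receptor segments were left out. Arntl was always included. Some genes that this rule selects are not reported here.

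The alternatives were DESeq2 1.42.0 or RLE factors for counts, a pseudocount of 0.1 for scaled values, no filter on low genes, the replicate number as a block, the groups of the comparison alone, an overlap threshold of 0.1, and leaving out each library in turn. Chosen after the data were seen were edgeR on estimated reads for liver and heart, and models that left out or adjusted for libraries carrying transcripts of another tissue. Such libraries had a marker sum of at least 50 CPM and over 10 times the tissue's median library, or over 5 times in a looser version that was added because a liver library lay just under the stricter limit. For fat the sums were also taken without the most abundant gene of the list, since Cyp2e1 made up 98.6% of the hepatocyte sum, and both limits were applied.

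Calls were tested on simulated data with 200 changed genes per tissue. At a 1.5-fold change limma recovered 46 of 100 genes in liver and 67 in heart, and edgeR 18 in fat and 20 in lung. At a 2-fold change the numbers were 71, 81, 49 and 64, with 4 to 6 false calls per tissue. A list of sex-chromosome genes was written but is not analysed here.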

Results

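RNA was sequenced from 64 mouse tissue libraries: 20 of liver, 20 of heart, 12 of inguinal white fat and 12 of lung. Within each tissue the libraries formed 4 groups, sedentary or trained mice with or without loss of Bmal1 in skeletal muscle. Bmal1, listed as Arntl, is a core transcription factor of the circadian clock. Each group held 5 libraries in liver and heart and 3 in fat and lung. Trained mice had run daily on a treadmill for 6 weeks, and tissue was taken 48 hours after the last bout. All mice carried the same Cre-positive, floxed Bmal1 genotype per the labels, and the controls are described as vehicle-treated, so a treatment used to induce the knockout cannot be separated from the knockout itself. Estimated depth, in M reads (megareads), was 12.4 to 20.7 per liver library, 14.1 to 21 per heart library, 19 to 31.2 per fat library and 18.7 to 35.7 per lung library. The time of day of collection is not given in the sources used here. Levels below are in CPM (deposited values brought here to the scale of counts per megaread), as mean ± SD over the libraries of a group, and fold changes are log2 with their standard error (SE).

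The targeted gene was examined first, although the muscle in which it was removed is not among the tissues measured. Arntl lies on chromosome 7 from 112806672 to 112913334 in the coordinates of the fat and lung tables, which match the build GRCm39. In liver, Arntl stood at 1.66 ± 0.798 in sedentary vehicle mice and 2.48 ± 0.779 in trained vehicle mice (n = 5 each). In the knockout groups it stood at 0.952 ± 0.439 when sedentary and 0.777 ± 0.367 when trained (n = 5 each). The difference between trained knockout and trained vehicle livers, a log2 fold change of -0.96 (SE 0.23), passed limma's test with an adjusted p of 0.034, and all 5 trained knockout livers lay below the range of the trained vehicle livers. The call was kept in 2 of the 10 fits that each left out a library, and its adjusted p was 0.0555 with no filter on low genes. In heart, Arntl lay under the filter for low genes, at 0.852 ± 0.475 and 0.646 ± 0.389 in sedentary and trained vehicle mice and 0.856 ± 0.209 and 0.896 ± 0.201 in the corresponding knockout groups (n = 5 each). In fat Arntl was 1.56 ± 0.275 in sedentary vehicle and 2.47 ± 0.629 in trained vehicle mice, and 2.08 ± 0.939 and 2.17 ± 0.351 in the corresponding knockout groups (n = 3 each). In lung Arntl was 2.78 ± 0.184 in sedentary vehicle and 1.82 ± 0.14 in sedentary knockout mice (n = 3 each), a log2 fold change of -0.59 (SE 0.21) with an edgeR adjusted p of 0.272.

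**Figure D1:**
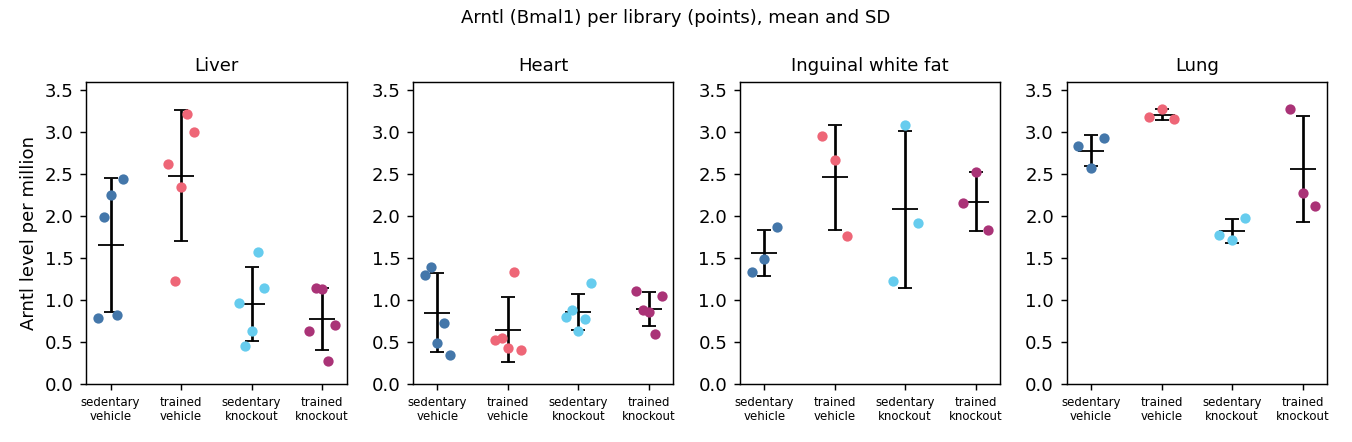
Arntl level in CPM (vertical axis, linear, from 0) in each library (points) of the 4 groups in liver, heart, inguinal white fat and lung, with the group mean (horizontal mark) and SD (bars). The trained knockout livers average 0.777 and the trained vehicle livers 2.48, while heart libraries of all groups stay at or below 1.4.

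In the heart, 6 weeks of training in vehicle mice raised 20 of 42 genes of oxidative phosphorylation, 3 of 20 glycolytic genes and 4 globin genes (adjusted p = 0.715 with an estimated correlation for each of these lists). Lower were many genes with long transcripts, among them those of titin and 2 potassium channels. Uqcrq, a subunit of respiratory complex III, rose from 410 ± 20.9 to 507 ± 31.8 (log2 0.31, SE 0.05, n = 5 each). The glycolytic enzyme gene Gapdh rose from 270 ± 12.3 to 334 ± 19.9 (log2 0.30, SE 0.05), and Hbb-bs, a beta globin of red blood cells, rose from 753 ± 104 to 1280 ± 265 (log2 0.75, SE 0.15). Ttn, which encodes titin, the giant spring protein of the sarcomere, fell by 0.27 on the log2 scale (SE 0.06), from 3690 ± 125 to 3050 ± 248. In each of these 4 genes all 5 trained libraries lay outside the range of the 5 sedentary ones.

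In all, limma called 1113 of 13455 genes between trained and sedentary vehicle hearts at an adjusted p under 0.05, 635 higher and 478 lower. These changes followed transcript length. Genes called higher had a median longest transcript of 1374 nucleotides and genes called lower one of 6427, against 3338.5 for the tested genes with a length, and the Spearman correlation of fold change with length across genes was -0.49 (genes are not independent replicates). Trained vehicle replicate 5 carried hepatocyte transcripts, 176.5 CPM against 14.69 in the next library of its group, and trained knockout replicate 5 carried brown fat transcripts, 253.4 CPM. Without these 2 libraries 1623 genes were called. Sedentary vehicle replicate 3 and trained vehicle replicate 1 also stood out in brown fat transcripts, at 174.6 and 142.2 CPM, and without all 4 libraries 521 genes were called. Leaving out trained vehicle replicate 1 alone left 418.

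**Figure D2:**
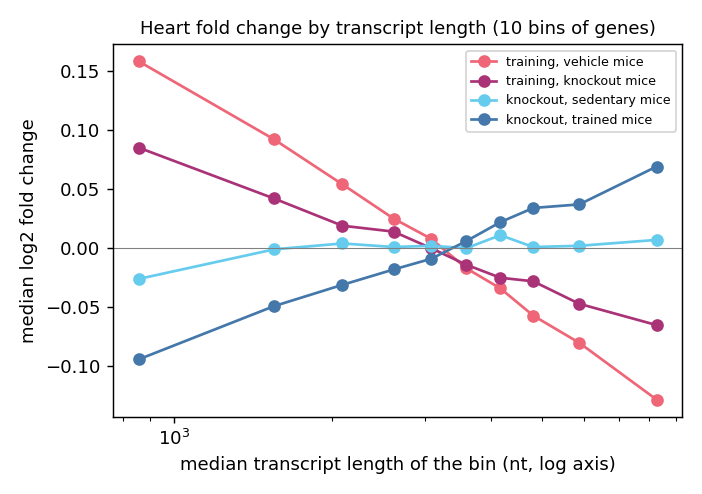
Median log2 fold change in heart (vertical axis) of 10 bins of genes against the median transcript length of the bin in nucleotides (horizontal axis, log scale), with a line for each comparison. For training in vehicle mice the medians fall from 0.158 in the bin of the shortest transcripts to -0.128 in that of the longest, and for the knockout in trained mice they rise from -0.094 to 0.069.

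Of the 42 measured genes of nuclear-encoded oxidative phosphorylation, 20 rose with training in vehicle hearts and none fell, with 28 higher and 1 lower when adjusted over the list alone. The list test (camera) gave an adjusted p of 1.38e-11 at its preset correlation between genes, and adjusted p = 0.715 with an estimated correlation. Besides Uqcrq, the complex I genes Ndufa2 (log2 0.34, SE 0.06), Ndufb9 (0.26, SE 0.05) and Ndufs4 (0.26, SE 0.05) were among the risers. These genes are short: their median transcript is 1386.5 nucleotides, their median log2 fold change was 0.161, and 1000 random lists matched for length had a median of 0.096, with 9 lists at or above the observed value. A length index of each library was the mean log2 level of long minus short transcripts among genes with an adjusted p over 0.5. With it in the model, 5 of the 20 members called stayed called. As the genes of the index were chosen for changing little in this same comparison, that model may remove too little of a length effect. In glycolysis 3 of 20 genes rose, Gapdh, Pgk1 (0.21, SE 0.05) and Tpi1 (0.16, SE 0.05), and 4 rose when adjusted over the list alone (camera adjusted p 0.0201; adjusted p = 0.715 with an estimated correlation).

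Of the 18 clock genes measured in heart, 4 rose and 1 fell with training in vehicle mice, and 4 were higher and 4 lower when adjusted over the list alone. Dbp, an output transcription factor of the clock, rose from 120 ± 17.4 to 157 ± 7.74 (log2 0.39, SE 0.08, limma adjusted p 0.0047). Nr1d1, the repressor also named Rev-erb alpha, rose from 45.2 ± 4.54 to 58.5 ± 6.38 (adjusted p 0.00752), and Ciart, a circadian repressor, from 8.92 ± 0.921 to 12.6 ± 1.92 (adjusted p 0.00662). Per2, of the core negative limb, fell from 36.5 ± 3.44 to 27.2 ± 2.53 (log2 -0.41, SE 0.08, adjusted p 0.00323). As members went both ways, the list as a whole did not pass (camera adjusted p 0.952; adjusted p = 0.989 with an estimated correlation). These 4 calls were kept in all 10 fits that left out a library.

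**Figure D3:**
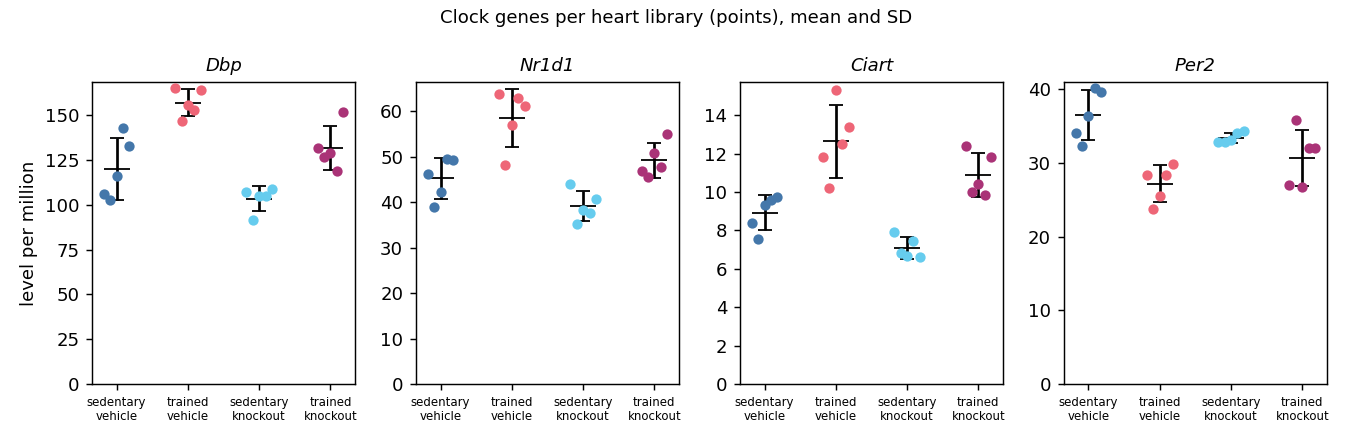
Level in CPM (vertical axis, linear, from 0) of the clock genes Dbp, Nr1d1, Ciart and Per2 in each heart library (points) of the 4 groups, with the group mean (horizontal mark) and SD (bars). All 5 trained vehicle hearts lie above the sedentary vehicle range in Dbp and Ciart and below it in Per2, with means of 157 and 120 for Dbp.

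Among other heart groups, all 4 globin genes rose with training in vehicle mice (Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2), making 4 of 8 erythroid genes, or 5 when adjusted over the list alone (camera adjusted p 0.000729; adjusted p = 0.715 with an estimated correlation). Their near-identical copies share reads, so the split between copies is uncertain. Of 23 ion channel and conduction genes 4 fell (5 when adjusted over the list alone), including the potassium channel genes Kcnj3 (log2 -0.42, SE 0.11) and Kcnd3 (-0.30, SE 0.09), with a camera adjusted p of 0.021 and adjusted p = 0.715 with an estimated correlation. Atrial transcripts, a list written after the data were seen, summed to 1009 to 4298 CPM in sedentary and 529 to 2461 in trained vehicle hearts. With that sum in the model Kcnj3 was at -0.18 (SE 0.06, adjusted p 0.111) and Kcnj5, also among the 4, went from -0.22 (SE 0.07) to -0.09 (SE 0.05, adjusted p 0.326). Kcnd3 was at -0.20 (SE 0.10, adjusted p 0.261), and Abcc9, the fourth, went from -0.21 (SE 0.06) to -0.30 (SE 0.06, adjusted p 0.0142). The troponin genes Tnnc1 (0.33, SE 0.07) and Tnni3 (0.28, SE 0.07) and Csrp3, a Z-disc protein gene (0.29, SE 0.06), rose while Ttn fell. Of 20 contraction and calcium handling genes 5 rose and 3 fell (5 and 4 when adjusted over the list alone), and the list did not pass (camera adjusted p 0.324; adjusted p = 0.872 with an estimated correlation). Erbb4, the neuregulin receptor (-0.51, SE 0.09), Ppara, a regulator of fatty acid oxidation (-0.43, SE 0.08), and Vegfa, an angiogenic growth factor (-0.25, SE 0.06), also fell. Larger single changes were those of the protocadherin gene Pcdhgc4, which rose from 1.73 ± 1.06 to 6.55 ± 2.91, and of Adamts8, a secreted protease gene, which fell from 3.7 ± 2.68 to 0.892 ± 0.393. Of the 10 fits that left out a library, 6 kept the call of Kcnj3, 5 that of Tpi1, 4 that of Adamts8, 3 that of Kcnj5 and 2 those of Kcnd3 and Abcc9.

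In knockout hearts, training raised Ciart, from 7.09 ± 0.568 to 10.9 ± 1.14 (log2 0.55, SE 0.09, n = 5 each), Cyba, a subunit of the NADPH oxidase, from 15.6 ± 0.69 to 20.7 ± 1.99 (0.38, SE 0.07), and Rps27rt, which resembles a ribosomal protein gene and can share reads with it, from 106 ± 9.91 to 141 ± 10.5 (0.40, SE 0.07). In each, all 5 trained libraries lay above the sedentary range. These 3 genes were the calls at this threshold, with limma adjusted p values of 0.0223, 0.0288 and 0.0223, and 1589 genes had an unadjusted p under 0.05. All 3 also rose in vehicle mice, where chance overlap would be 0.142 genes (Fisher's exact test, one-sided, p 0.000105). That test takes genes as independent, which they are not, and both comparisons share the variance estimate of each gene. Of the 1113 genes called in vehicle hearts, 984 (88.4%) moved the same way in knockout hearts, with a median change of 0.091 in that direction against 0.257 in vehicle mice. As the genes were chosen for passing in vehicle mice, the vehicle median is raised by that choice. The 2 medians therefore cannot show a weaker response in knockout hearts. The 2 training comparisons share no libraries, and across all genes their fold changes correlated with a Pearson r of 0.313. In the other tissues that r was -0.106 in liver, -0.177 in fat and -0.043 in lung. Fold change also followed transcript length in knockout hearts (Spearman correlation -0.352 across genes). No gene was called without trained knockout replicate 5 and trained vehicle replicate 5, and 92 were called without sedentary knockout replicate 4. Of the 10 fits that left out a library, 4 kept the call of Ciart and 3 those of Cyba and Rps27rt.

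The difference between the training effects of knockout and vehicle hearts was tested directly. Pgk1, a glycolytic enzyme gene, had the training effect of knockout hearts lower by 0.29 on the log2 scale (a difference of -0.29, SE 0.07), Mrps17, of the mitochondrial ribosome, had -0.30 (SE 0.07), and Cox19, a cytochrome oxidase assembly gene, -0.36 (SE 0.08). None passed: the adjusted p was 0.524 for each, limma called 0 genes and edgeR on estimated reads called 0, with 1085 genes at an unadjusted p under 0.05. The smaller number of calls in knockout hearts is therefore not shown to be a different response.

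In sedentary hearts, the knockout was accompanied by no called gene. The lowest p values belonged to the alpha globin genes Hba-a1, at 694 ± 102 in knockout and 425 ± 57.1 in vehicle mice (log2 0.71, SE 0.14, n = 5 each), and Hba-a2 (0.69, SE 0.14). H2-Ab1, of antigen presentation, stood at 21.8 ± 3.91 against 34 ± 4.87 (-0.62, SE 0.13). The limma adjusted p values were 0.172 for both globin genes and 0.175 for H2-Ab1. limma and edgeR on estimated reads each called 0 genes, and 880 had an unadjusted p under 0.05. Of 8 erythroid genes all had a positive fold change (median 0.654), 0 were called and 7 were higher when adjusted over the list alone (camera adjusted p 1.38e-11; adjusted p = 0.367 with an estimated correlation). Of the 31 extracellular matrix genes 29 had a negative fold change, with a median of -0.131; none was called and 3 were lower when adjusted over the list alone (camera adjusted p 2.73e-09; adjusted p = 0.715 with an estimated correlation).

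In trained hearts, knockout mice had lower levels of 5 of 31 extracellular matrix genes than vehicle mice (adjusted p = 0.715 with an estimated correlation for the list). Sparc, a collagen-binding matrix protein gene, was 165 ± 18.7 against 228 ± 25.3 (log2 -0.46, SE 0.07, n = 5 each). The basement membrane collagen genes Col4a1 (-0.36, SE 0.06) and Col4a2 (-0.30, SE 0.06) and the fibrillar collagen gene Col3a1 (-0.51, SE 0.12) were lower as well. Pgk1 was 86.5 ± 5.05 against 108 ± 6.1 (-0.31, SE 0.05), and the apelin receptor gene Aplnr was 15.4 ± 2.56 against 23.7 ± 3.51 (-0.60, SE 0.13). C7, of the complement cascade, was higher, at 17.2 ± 1.72 against 10.9 ± 2.53 (0.64, SE 0.14).

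Of 31 matrix genes 5 were called lower in trained knockout hearts, and 12 when adjusted over the list alone (camera adjusted p 0.00000204; adjusted p = 0.715 with an estimated correlation). For oxidative phosphorylation 1 of 42 genes, Ndufs4, was called lower (-0.23, SE 0.05), and 11 when adjusted over the list alone (camera adjusted p 9.31e-09; adjusted p = 0.715 with an estimated correlation). In total limma called 70 genes, 22 higher and 48 lower. The calls of Sparc (adjusted p 0.00919) and Pgk1 (0.00552) were kept in all 10 fits that left out a library, that of Col4a1 in 6, that of Col4a2 in 4, those of Col3a1, Aplnr and C7 in 3 and that of Ndufs4 in 2. The comparison uses the same 5 trained vehicle libraries as the training comparison above, so the 2 results are not independent, and fold change followed transcript length with the opposite sign (Spearman correlation 0.329 across genes). The count was 500 without the 2 libraries that carried hepatocyte or brown fat transcripts, 88 without all 4, 4 without trained vehicle replicate 2 and 0 in a fit of these 2 groups alone. Brown fat transcripts without Cidea, the list's most abundant, summed to 57.05, 34.37, 2.087, 50.2 and 212.2 CPM in the trained knockout hearts. In the trained vehicle hearts they summed to 108.1, 0.9687, 3.768, 4.392 and 5.769. Trained knockout replicates 1, 2 and 4 stayed in the fits that left out libraries for such transcripts. Those fits therefore cannot show that the comparison is free of them.

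In the liver of trained mice, 5 of 17 heat shock genes were lower and 2 of 16 macrophage genes higher in knockout than in vehicle animals (adjusted p = 0.963 with an estimated correlation for both lists). Hspa1b, the inducible Hsp70 chaperone, was 28.8 ± 3.84 against 90.8 ± 62.7 (log2 -1.35, SE 0.31, n = 5 each), and its co-chaperone gene Hsph1 was 50 ± 14.2 against 98.9 ± 31.3 (-0.96, SE 0.21). Marco, a scavenger receptor gene of macrophages, was 14.5 ± 10.7 against 2.36 ± 2.1 (2.07, SE 0.51), and Cd5l, a protein secreted by macrophages, was 82.3 ± 46.8 against 30.2 ± 11.6 (1.33, SE 0.34). Cish, a feedback inhibitor of cytokine and growth hormone signalling, was 45.3 ± 16.5 against 6.37 ± 2.61 (2.65, SE 0.60). Bcl6, a transcriptional repressor, was 20.8 ± 13.2 against 62.7 ± 8.17 (-1.82, SE 0.48), and the major urinary protein gene Mup10 was 9.51 ± 3.06 against 66.6 ± 37.8 (-2.43, SE 0.51). Mup genes are near-identical copies, so reads of Mup10 can be shared. Of the 10 fits that each left out a library, the call of Bcl6 was kept in 0, those of Marco and Cd5l in 2, that of Cish in 3, and those of Hspa1b, Hsph1 and Mup10 in 5.

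All 17 heat shock genes had a negative fold change in trained knockout livers, 5 were called lower, and 12 were lower when adjusted over the list alone (camera adjusted p 3.81e-09; adjusted p = 0.963 with an estimated correlation). Hsp90aa1 (-0.85, SE 0.19) and Ahsa1, an Hsp90 cofactor (-0.40, SE 0.10), were among the called. Of 22 endoplasmic reticulum stress genes, Creld2 (-1.20, SE 0.31) and Ddit3 (-0.83, SE 0.22) were called lower and Chac1, which degrades glutathione, higher (1.05, SE 0.24). When adjusted over the list alone 9 were lower and 1 higher (camera adjusted p 0.000651; adjusted p = 0.963 with an estimated correlation). Of 16 macrophage and inflammation genes, Marco and Cd5l were called higher, and 14 were higher and 1 lower when adjusted over the list alone (camera adjusted p 0.000016; adjusted p = 0.963 with an estimated correlation). Of 18 clock genes Arntl was lower and Nr1d2, the repressor Rev-erb beta, was higher, at 139 ± 30.1 against 83 ± 11 (0.72, SE 0.13, limma adjusted p 0.0233), and the list as a whole did not pass (camera adjusted p 0.991). The fits that left out a library kept the call of Creld2 in 1 of 10, Ddit3 in 2, Chac1 in 3, Hsp90aa1 and Ahsa1 in 4 and Nr1d2 in 6.

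**Figure D4:**
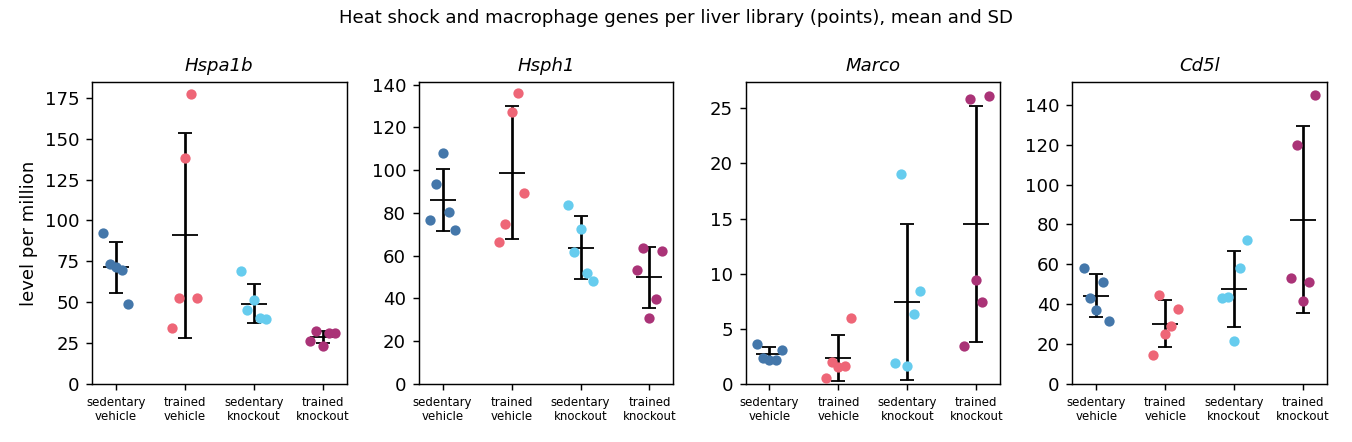
Level in CPM (vertical axis, linear, from 0) of the heat shock genes Hspa1b and Hsph1 and the macrophage genes Marco and Cd5l in each liver library (points) of the 4 groups, with the group mean (horizontal mark) and SD (bars). The trained vehicle livers spread widely in Hspa1b (SD 62.7 around 90.8), and all 5 trained knockout livers lie below them.

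limma called 337 of 12818 genes in this liver comparison, 199 higher and 138 lower. Trained vehicle replicate 1 carried brain and hypothalamus transcripts, 415.7 CPM against 43.43 in the next library of its group, and trained knockout replicate 2 carried skeletal muscle transcripts, 215.8 against 6.472. Without these 2 libraries 10 genes were called, and without sedentary knockout replicate 4 as well, which carried brain transcripts at 313.8 CPM, 8 were called. Of the single omissions 9 of 10 moved the count by over 1.5 times, from 4 without trained vehicle replicate 3 to 595 without trained vehicle replicate 2, and with no filter on low genes 20 were called.

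In knockout livers, training lowered Ccnd1, which encodes cyclin D1 of the cell cycle, from 39.3 ± 7.57 to 14.3 ± 1.03 (log2 -1.38, SE 0.20, n = 5 each). Lgals1, a galectin gene, fell from 33.7 ± 9.55 to 15.2 ± 2.51 (-1.06, SE 0.18), and Cyp2c38, a cytochrome P450 gene of a family with near-identical copies, fell from 38.2 ± 10.7 to 16.8 ± 5.59 (-1.13, SE 0.20). These 3 genes were the calls, with limma adjusted p values of 0.00654, 0.0327 and 0.0403, and 1507 genes had an unadjusted p under 0.05. The call of Ccnd1 was kept in all 10 fits that left out a library, that of Lgals1 in 3 and that of Cyp2c38 in 2. Without the 2 libraries with transcripts of another tissue 1 gene was called, and without all 3 none was, with edgeR on estimated reads calling 3.

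In vehicle livers, no gene passed for training. The smallest p values were those of Rpl36a, a ribosomal protein gene, at 7.83 ± 0.849 in trained and 13.4 ± 2.03 in sedentary mice (log2 -0.70, SE 0.13, n = 5 each), and of Hmgcs1, which makes the precursor of the sterol pathway, at 148 ± 39.1 against 275 ± 71.8 (-0.89, SE 0.18), both with a limma adjusted p of 0.208. Cyp26a1, the retinoic acid hydroxylase gene, had a log2 fold change of -1.06 (SE 0.22, adjusted p 0.212). Of the 24 cholesterol synthesis genes 23 had a negative fold change, with a median of -0.291, and 9 were lower when adjusted over the list alone although none was called over all genes (camera adjusted p 2.23e-11; adjusted p = 0.963 with an estimated correlation). limma and edgeR on estimated reads each called 0 genes, and 886 had an unadjusted p under 0.05.

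In sedentary livers, knockout and vehicle mice differed in no called gene. The smallest p values were those of Prob1, at 7.66 ± 1.69 against 14 ± 2.11 (log2 -0.80, SE 0.15, n = 5 each), and Mmd2, at 10.5 ± 1.93 against 5.06 ± 0.97 (0.92, SE 0.18), both with a limma adjusted p of 0.251. Of 17 heat shock genes 16 had a negative fold change (median -0.21), 0 were called and 1 was lower when adjusted over the list alone (camera adjusted p 0.000016; adjusted p = 0.963 with an estimated correlation). limma and edgeR on estimated reads each called 0 genes, and 616 had an unadjusted p under 0.05.

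The training effect differed between knockout and vehicle livers in 1 gene, Rps2-ps8, a pseudogene of the ribosomal protein gene Rps2 that can share its reads. It was named after its values were seen. Its level was 3.121 ± 0.4201 in trained and 6.516 ± 1.881 in sedentary vehicle mice, and 6.426 ± 0.8358 and 4.004 ± 1.131 in the corresponding knockout groups (difference 1.43, SE 0.23, limma adjusted p 0.0491). limma called 1 gene and 1311 had an unadjusted p under 0.05, while edgeR on estimated reads, a fit without the libraries that carried transcripts of another tissue and a fit with no filter on low genes each called 0.

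In inguinal white fat of trained mice, 6 of 20 lymphocyte genes and 6 of 27 macrophage genes were lower and 3 of 22 adipocyte genes higher in knockout than in vehicle animals (adjusted p = 0.938 with an estimated correlation for each list). Cr2, a complement receptor of B cells, was 0.344 ± 0.194 against 3.45 ± 3.15 (log2 -3.32, SE 0.76, n = 3 each), and Pax5, the transcription factor of B cell identity, was 1.53 ± 1.07 against 14.9 ± 13.6 (-3.28, SE 0.82). C1qc, of complement C1q made by macrophages, was 219 ± 45.1 against 397 ± 55.2 (-0.86, SE 0.14), and Lyz2, a lysozyme gene of myeloid cells, was 885 ± 294 against 2360 ± 256 (-1.42, SE 0.27). Plin4, which coats lipid droplets, was 5180 ± 882 against 3160 ± 434 (0.71, SE 0.17), and Dio2, which activates thyroid hormone, was 1.89 ± 0.591 against 9.97 ± 0.104 (-2.38, SE 0.57). In each of these 6 genes all 3 knockout libraries lay outside the vehicle range.

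Of 20 B and T lymphocyte genes 6 were called lower in trained knockout fat, and 10 when adjusted over the list alone (camera adjusted p 0.00018; adjusted p = 0.938 with an estimated correlation). The 3 trained vehicle libraries differed among themselves in these genes, as the SDs of Cr2 and Pax5 show. Log2 of the list's summed CPM plus 1 was 10.45, 8.85 and 9.4 in trained vehicle and 8.9, 9.29 and 8.14 in trained knockout libraries. These ranges overlapped, and trained vehicle replicate 1 was the highest. Of 27 macrophage and inflammation genes 6 were called lower, with C1qa (-0.71, SE 0.13) and C1qb (-0.85, SE 0.16) among them, and 10 were lower when adjusted over the list alone (camera adjusted p 0.00165; adjusted p = 0.938 with an estimated correlation). Of 22 adipocyte genes all had a positive fold change and 3 were called higher, Plin4, Aqp7, the glycerol channel (0.72, SE 0.18), and Trarg1, a regulator of glucose transporter trafficking (0.73, SE 0.18). When adjusted over the list alone 10 were higher (camera adjusted p 0.0000000879; adjusted p = 0.938 with an estimated correlation). The endothelial list had a median of 0.549 with 1 of 25 genes called, Car4 (1.16, SE 0.24), and 1 when adjusted over the list alone (camera adjusted p 0.0000242; adjusted p = 0.938 with an estimated correlation).

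**Figure D5:**
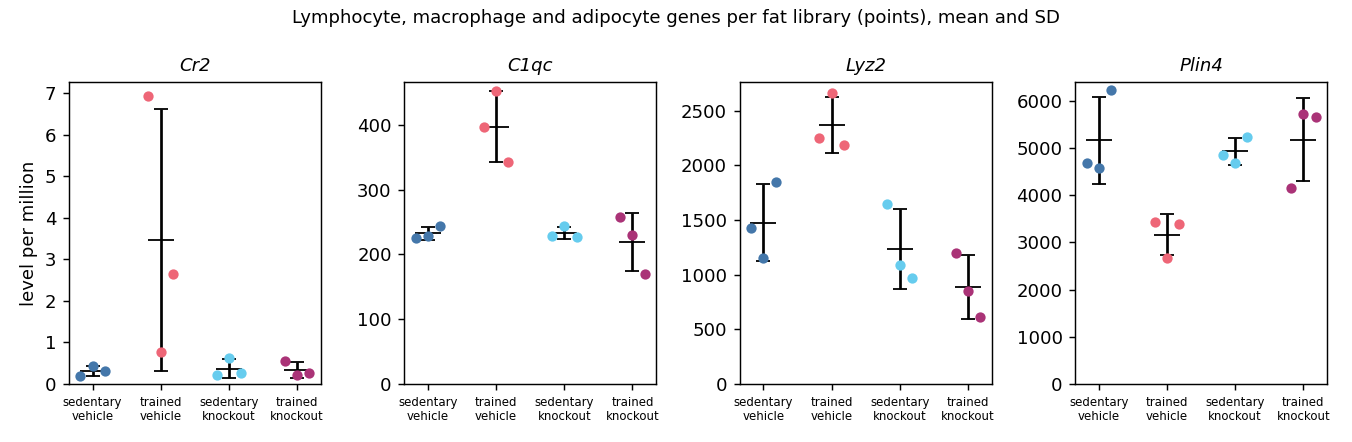
Level in CPM (vertical axis, linear, from 0) of the B cell gene Cr2, the macrophage genes C1qc and Lyz2 and the adipocyte gene Plin4 in each inguinal fat library (points) of the 4 groups, with the group mean (horizontal mark) and SD (bars). The trained vehicle libraries stand apart, with means of 397 in C1qc and 2360 in Lyz2, and scatter in Cr2 (3.45, SD 3.15).

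edgeR called 685 of 15448 genes in this fat comparison, 130 higher and 555 lower, and DESeq2 called 1968, 740 higher and 1228 lower. Every single omission moved edgeR's count by over 1.5 times, from 0 without trained vehicle replicate 1 to 1630 without trained knockout replicate 1, and none of the genes named here kept its call in more than 1 of 6 such fits. Trained knockout replicate 2 carried hepatocyte transcripts, 4263 CPM without Cyp2e1 against 50.11 in the next library of its group, and edgeR called 0 genes without it. Without that library and sedentary knockout replicate 1, which carried 528.4, edgeR called 1, and it also called 1 when sedentary vehicle replicate 1 (294.2) was left out as well.

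In sedentary fat, knockout mice had higher levels of Thbs1, a matrix glycoprotein, at 259 ± 132 against 37.4 ± 11.7 (log2 2.79, SE 0.48, n = 3 each), and of the imprinted gene Peg10, at 25.7 ± 5.4 against 7.53 ± 1.23 (1.77, SE 0.21). Lower were Acsm3, a mitochondrial acyl-CoA synthetase gene, at 10.9 ± 6.14 against 69.1 ± 23.9 (-2.66, SE 0.49), and Angpt1, a vessel-stabilising ligand, at 11 ± 2.73 against 31 ± 6.32 (-1.49, SE 0.23). Of 31 extracellular matrix genes Thbs1 and Col18a1 (0.58, SE 0.10) were called higher, and 13 were when adjusted over the list alone (camera adjusted p 0.000000503; adjusted p = 0.938 with an estimated correlation). Of 25 proliferation genes 24 had a positive fold change (median 0.854), 0 were called over all genes and 11 were higher when adjusted over the list alone (camera adjusted p 3.11e-10; adjusted p = 0.938 with an estimated correlation). edgeR called 86 genes, 66 higher and 20 lower, and DESeq2 921, 587 higher and 334 lower. edgeR's count was 0 without sedentary vehicle replicate 2 and 199 without sedentary knockout replicate 1, and all 6 single omissions moved it by over 1.5 times. Of these 6 fits, 2 kept the call of Peg10 and 1 those of Thbs1, Acsm3, Angpt1 and Col18a1. A sum of hepatocyte transcripts was lower in all 3 knockout libraries (1094 to 2290 CPM) than in the vehicle libraries (3795 to 4880), but 98.6% of it is Cyp2e1 (log2 -1.57, SE 0.33, adjusted p 0.0556). The other 19 transcripts summed to 528.4, 11.01 and 117.4 in knockout and 294.2, 22.75 and 22.14 in vehicle libraries. edgeR called 273 genes without sedentary knockout replicate 1 and trained knockout replicate 2, and 0 when sedentary vehicle replicate 1 was left out as well.

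In vehicle fat, training was accompanied by no called gene. Among the lowest p values, Cbr2 was 104 ± 10.7 in trained and 53.2 ± 1.99 in sedentary mice (log2 0.96, SE 0.13, n = 3 each), and Lyve1, a hyaluronan receptor, was 132 ± 2.89 against 68.1 ± 3.72 (0.95, SE 0.13), both with an edgeR adjusted p of 0.103. Of 22 adipocyte genes all had a negative fold change (median -0.403), and 12 were lower when adjusted over the list alone, with 0 called over all genes (camera adjusted p 1.42e-12; adjusted p = 0.938 with an estimated correlation). Of 27 macrophage genes 26 had a positive fold change, and 8 were higher when adjusted over the list alone, with 0 called over all genes (camera adjusted p 0.00000316; adjusted p = 0.938 with an estimated correlation). Of 20 B and T lymphocyte genes 19 had a positive fold change (median 1.795), 0 were called and 11 were higher when adjusted over the list alone (camera adjusted p 0.0000341; adjusted p = 0.938 with an estimated correlation). Log2 of the list's summed CPM plus 1 was 10.45, 8.85 and 9.4 in trained and 8.5, 8.92 and 8.94 in sedentary libraries. Trained vehicle replicate 2, at 8.85, lay within the sedentary range. All 42 oxidative phosphorylation genes had a negative fold change (median -0.265), with 0 called and 2 lower when adjusted over the list alone (camera adjusted p 3.26e-15; adjusted p = 0.938 with an estimated correlation). edgeR called 0 genes, DESeq2 747, and 2785 had an unadjusted p under 0.05 with edgeR. In a fit of these 2 groups alone edgeR called 216. The comparison uses the same 3 trained vehicle libraries as that of the knockout in trained fat, so the 2 results are not independent.

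In knockout fat, Peg10 was 9.25 ± 1.35 in trained and 25.7 ± 5.4 in sedentary mice (log2 -1.47, SE 0.21, n = 3 each), and Tsc22d2 was 55.2 ± 7.54 against 104 ± 20.3 (-0.91, SE 0.13), both with an edgeR adjusted p of 0.0718, so neither passed. The same sedentary knockout libraries entered the knockout comparison in sedentary fat, so the 2 changes of Peg10 are not independent. edgeR called 0 genes for training in knockout fat, DESeq2 573, and 2516 had an unadjusted p under 0.05. The difference between the training effects of knockout and vehicle fat was lowest in p for Tmem132a (-1.61, SE 0.19, adjusted p 0.0503) and Lyve1 (-1.50, SE 0.19, adjusted p 0.0555). For this difference edgeR called 0 genes, DESeq2 724, and 2848 had an unadjusted p under 0.05. These zeros depended on single libraries. edgeR called 472 genes for the difference without trained knockout replicate 1, and 92 for training in knockout fat without sedentary knockout replicate 2. No gene was called by edgeR for training in both vehicle and knockout fat, as none was called in either, and DESeq2 called 36 in both.

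In the lung, training in vehicle mice lowered 30 genes and raised 3, and of 20 lymphocyte genes 1 was called lower (adjusted p = 0.858 with an estimated correlation for the list). Gpr174, a receptor of lymphocytes, fell from 8.3 ± 2.87 to 1.74 ± 0.765 (log2 -2.24, SE 0.35, n = 3 each), Btla, an inhibitory receptor of lymphocytes, from 31.9 ± 7.06 to 9.31 ± 0.859 (-1.78, SE 0.25), and Bank1, a B cell scaffold gene, from 14.7 ± 6.7 to 3.37 ± 1.75 (-2.11, SE 0.38). Ifi209, an interferon-inducible gene, fell from 29.3 ± 6.13 to 8.81 ± 1.16 (-1.73, SE 0.20). Pfkm, the muscle form of phosphofructokinase, rose from 22.8 ± 2.32 to 39.7 ± 8.51 (0.80, SE 0.14), and Unc45b, a myosin chaperone of striated muscle, from 37.5 ± 3.45 to 53.7 ± 3.26 (0.52, SE 0.09). In each, all 3 trained libraries lay outside the sedentary range.

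Of 20 B and T lymphocyte genes 1 was called lower with training in vehicle lungs, and 17 were when adjusted over the list alone (camera adjusted p 3.41e-12; adjusted p = 0.858 with an estimated correlation). The heart muscle genes that lung tissue can carry had a median of 0.938, with 0 of 15 called and 5 higher when adjusted over the list alone (camera adjusted p 0.00000381; adjusted p = 0.858 with an estimated correlation). Erythroid genes had a median of 0.778, with 0 of 12 called and 8 higher when adjusted over the list alone (camera adjusted p 0.0000000505; adjusted p = 0.858 with an estimated correlation). All 25 proliferation genes had a negative fold change (median -0.703), with 0 called over all genes or adjusted over the list alone (camera adjusted p 0.000000712; adjusted p = 0.858 with an estimated correlation). edgeR called 33 of 16151 genes, 3 higher and 30 lower, and DESeq2 411, 170 higher and 241 lower. edgeR's count was 0 without trained vehicle replicate 1 and 206 without sedentary vehicle replicate 1, and all 6 single omissions moved it by over 1.5 times. Of these 6 fits, 4 kept the call of Ifi209, 2 those of Gpr174 and Bank1 and 1 those of Btla, Pfkm and Unc45b. Mean depth was 30.6 M reads in trained and 21.17 M reads in sedentary vehicle lungs.

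The other lung comparisons had no called gene. In knockout lungs, Rps21, a ribosomal protein gene, was 61.6 ± 13.9 in trained and 34.3 ± 2.8 in sedentary mice (log2 0.85, SE 0.15, n = 3 each, edgeR adjusted p 0.24). All 42 oxidative phosphorylation genes had a positive fold change there (median 0.398), with 0 called and 11 higher when adjusted over the list alone (camera adjusted p 1.7e-10; adjusted p = 0.858 with an estimated correlation), and fold change followed transcript length with a Spearman correlation of -0.529 across genes. Fold changes were also positive in 15 of 15 heart muscle genes (median 0.757, camera adjusted p 0.00281), 21 of 22 adipocyte genes (0.681, 0.00254) and 17 of 17 club and ciliated airway genes (0.533, 0.00351). In these 3 lists 0 genes were called over all genes and 0 when adjusted over the list alone (adjusted p = 0.858 with an estimated correlation for each). In sedentary lungs, Rasip1, of endothelial junctions, was 243 ± 29.1 in knockout and 141 ± 19.3 in vehicle mice (0.78, SE 0.12), and Spry4, a feedback inhibitor of growth factor signalling, was 37.2 ± 6.7 against 18.2 ± 2.64 (1.03, SE 0.17), both with an adjusted p of 0.175. In trained lungs, Lama3, a laminin gene, was 69 ± 9.43 in knockout and 139 ± 31.2 in vehicle mice (-1.01, SE 0.20, adjusted p 0.282), and fold change followed transcript length with a correlation of -0.549. For the difference between the training effects of knockout and vehicle lungs the smallest p values were those of Arhgap15 (1.27, SE 0.20) and Slfn2 (1.21, SE 0.21), both with an adjusted p of 0.207, so neither passed. edgeR called 0 genes in each of these 4 comparisons, with 2688, 2200, 2620 and 2451 genes at an unadjusted p under 0.05, and DESeq2 called 145, 265, 101 and 296 in the same order. edgeR called no gene for training in both vehicle and knockout lungs, and DESeq2 called 3. Of the 33 genes that edgeR called in vehicle lungs, 23 (69.7%) moved the same way in knockout lungs. Their median change in that direction was 0.026, against 1.11 in vehicle mice, where the choice of genes raises the median.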

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

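The groups and the rule that sets a library apart were fixed beforehand, while the marker lists of other tissues with their limits, the tests on cell types in fat, the tests of blood in sedentary hearts and of the atrial share, and the comparison with a shuffled covariate were chosen after results were seen.

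In several groups of 5 libraries 1 library lay far from the rest. Chance sets a library apart in about 1 in 20 groups, and for the named genes this was so in 9 of 177 groups. Arntl was 1.33 CPM in trained vehicle heart 4 (nearest library 0.545), and Marco 6.0 in trained vehicle liver 5 (nearest 2.02). Cyp2c38 was 19.5 in sedentary knockout liver 2 (nearest 38.9) and 26.5 in trained knockout liver 4 (nearest 15.6). In heart, Ndufb9 was 364.0 in sedentary vehicle 2 (nearest 337), Pgk1 89.1 in sedentary vehicle 4 (nearest 93.1), Spock2 24.3 in trained knockout 5 (nearest 20.3), Kcnd3 19.5 in trained vehicle 5 (nearest 15.4) and Abcc9 219.0 in trained vehicle 4 (nearest 235).

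Sums of marker transcripts of other tissues set a library apart in 14 of 36 groups of liver and heart. In heart, brown fat transcripts summed to 174.6 CPM in sedentary vehicle 3 (nearest 25.88), 253.4 in trained knockout 5 (nearest 80.83) and 142.2 in trained vehicle 1 (nearest 23.93), and hepatocyte transcripts to 176.5 in trained vehicle 5 (nearest 14.69). Airway transcripts summed to 109.8 in trained knockout heart 5 (nearest 14.23), and brain and hypothalamus transcripts to 149.0 in sedentary knockout heart 5 (nearest 85.7), 153.6 in sedentary vehicle heart 2 (nearest 83.06) and 158.7 in trained knockout heart 3 (nearest 85.09). In liver, brain and hypothalamus transcripts summed to 313.8 in sedentary knockout 4 (nearest 50.42) and 415.7 in trained vehicle 1 (nearest 43.43), and airway transcripts in these 2 libraries to 4.093 (nearest 0.9208) and 7.027 (nearest 0.8912). Skeletal muscle transcripts summed to 215.8 in trained knockout liver 2 (nearest 6.472), and to 1.458 in sedentary knockout liver 4 (nearest 0.8632). No library of fat or lung passed the limits for such sums, but without Cyp2e1, which made up 98.6% of the hepatocyte sum in fat, 3 fat libraries did: trained knockout 2 with 4263 CPM and sedentary knockout 1 with 528.4 passed the 10-fold limit, and sedentary vehicle 1 with 294.2 the 5-fold limit. Brown fat sums without Cidea passed the 5-fold limit in 3 further hearts, sedentary knockout 3 (57.4), trained knockout 1 (57.05) and trained knockout 4 (50.2), which no fit left out together. How the transcripts came into these libraries was not tested.

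The training effect on Rps2-ps8 differed between knockout and vehicle livers by 1.43 (SE 0.23, limma adjusted p 0.0491), in the test of the difference itself. Its adjusted p lay next to the threshold, and none of the alternatives without filter, with a replicate block, with edgeR or without libraries carrying other transcripts called a gene.

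Training in vehicle hearts moved short and long transcripts in opposite directions, and the length index of a library, long minus short, stood apart in 2 of 4 groups: 0.715 in sedentary knockout 4 (nearest 0.777) and 0.616 in trained knockout 5 (nearest 0.711). With the index in the model 278 of the 1113 calls were kept. The median fold change of the called genes went from 0.257 (SE 0.065) to 0.217 (SE 0.064). Losing most calls had been set beforehand as a sign of transcript length or RNA integrity, and most were lost. Shuffling the index within groups kept 280 to 1050 calls with a median of 694, and 0 of 20 shuffled fits kept as few as 278. The lowest shuffled count lay close to 278, so the margin is narrow there. Clock calls went from 5 to 4, and those of oxidative phosphorylation from 20 to 5. The index was built from genes with a high adjusted p in this same comparison. That choice favours a small difference of the index between trained and sedentary vehicle hearts, which was -0.038. The fit may therefore remove too little of a length effect. The pattern may follow transcript length or RNA integrity, but this fit cannot decide how much of it does. With the knockout in sedentary hearts the erythroid sum rose by 0.64 (SE 0.168), against 0.652 (SE 0.168) with training. The 1109 called genes outside the erythroid list moved there by 0.007 (SE 0.029) in the direction of their call, where blood would give 0.249. These values argue against blood as the cause of those calls only if the knockout did not move the genes the other way. That was not tested, and the SE leaves out that the genes were chosen with the same sedentary vehicle libraries. With the erythroid sum in the model 107 calls were kept while the median fold change went from 0.257 (SE 0.065) to 0.26 (SE 0.089), so calls ended because the error rose. Losing most calls had been set beforehand as a sign of blood. That test cannot decide, as the sums of the groups did not overlap and 12 of 20 shuffled sums kept as few. A smaller atrial share was tested as well. With the atrial sum in the model (456 calls kept, median fold change 0.242, SE 0.071) the called genes still moved by 0.238 (SE 0.033), against 0.253 (SE 0.029) without it. These genes were chosen by this same comparison, which favours genes with little spread within groups. The SE leaves that choice out, so the test cannot decide. Blood stays open for the 4 globin calls, which are part of the sum, and for the other calls if the knockout moved them the other way. Atrial share stays open too, above all for Kcnj3 and Kcnj5, as does a response of the heart to training.

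In fat of trained mice, 6 lymphocyte and 6 macrophage genes were lower and 3 adipocyte genes higher with the knockout (adjusted p = 0.938 with an estimated correlation for each list), and edgeR called 0 genes without trained knockout 2, the library with 4263 CPM of hepatocyte transcripts. The called genes outside the lymphocyte list had a median level, in the direction of their call, of -0.48 to -0.42 in trained vehicle libraries. It was 0.07 to 0.44 in trained knockout and -0.07 to 0.28 in sedentary libraries, so the trained vehicle group stood apart. Lymph node or lymphocytes were tested as the whole cause of the 679 calls outside the B and T lymphocyte list. With the list's sum in the model the median level of these genes still moved by 0.651 (SE 0.119) in the direction of their call, against 0.718 (SE 0.108) without it. The genes were chosen by this same comparison, which favours genes with little spread within groups. As the SE leaves that choice out, the test cannot decide. In that model 3 of 685 calls were kept, as the median fold change went from 0.719 (SE 0.154) to 0.652 (SE 0.169), so the change shrank and its error grew. Losing most calls had been set beforehand as a sign of lymphocytes, but shuffled sums kept a median of 1, so this cannot decide either. A larger adipocyte share that dilutes every other cell type would lower both the endothelial and the macrophage list. The endothelial median (0.549) exceeded the macrophage median (-0.708) by 1.26 (SE 0.347). This SE is taken over genes, which are not independent replicates, so it does not measure the spread between mice and the test cannot decide. Lymph node or lymphocytes in some vehicle samples stay open for the called genes, as do a larger adipocyte share and an effect of the knockout on immune cells in fat.

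In lung, training in vehicle mice lowered 30 genes, 1 of them among 20 lymphocyte genes (adjusted p = 0.858 with an estimated correlation for the list). The 29 lower genes outside the lymphocyte list followed it within groups with a median correlation of 0.59, against 0.016 for all tested genes; this lies between the limits set for the test, so fewer lymphocytes in the sample could be the cause or not. After thinning to 18668276 reads per library the median size of the change was 1.08 against 1.11. Random thinning is not expected to shift a fold change, so this size cannot decide whether depth is a cause. With depth made equal 26 genes were called, against 33 before. A response of lung lymphocytes to training stays open.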

How the results depend on the processing

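Each result was refitted with 1 choice changed at a time; edgeR on estimated reads and the models concerning libraries with transcripts of another tissue were chosen after seeing the data. No result reversed its direction. Counts stayed within 1.5 times the value reported in every tissue with a pseudocount of 0.1 (liver and heart) or RLE factors (fat and lung), and named genes kept their calls in 99 and 63 cases, with 0 and 4 lost. DESeq2 kept 65 and lost 0, edgeR on estimated reads 88 and 11, covariates 85 and 14, and the replicate block 125 and 41. With no filter 98 were kept and 68 lost, and with the compared groups alone 84 and 78. Without libraries carrying other transcripts, liver and heart kept 72 and lost 27 (10-fold limit) or 51 and 48 (5-fold). Fat, with sums without Cyp2e1, kept 21 and lost 30, or 5 and 46. For changes below, the cause was not tested unless fewer libraries or genes entered the fit.

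DESeq2 called 747 genes in fat for training in vehicle mice, 573 for training in knockout mice, 921 and 1968 for the knockout in sedentary and trained mice and 724 for the difference in training effect. In lung it called 411, 145, 265, 101 and 296 in the same order, and the genes shared by both training comparisons were 36 in fat and 3 in lung. Fits of the groups compared alone, with fewer libraries, gave 1, 1 and 509 genes in liver (training in knockout mice, knockout in sedentary and in trained mice), 6 and 0 in heart (knockout in sedentary and in trained mice), 216 and 12 in fat (training in vehicle mice, knockout in sedentary mice) and 6 in lung (training in vehicle mice). Without a filter, with more genes tested, liver gave 1 for training in knockout mice, 20 for the knockout in trained mice and 0 for the difference, heart 14 for the knockout in trained mice, and fat 33 and 418 for the knockout in sedentary and trained mice. Libraries of the same replicate number correlated on average by -0.048 in liver, 0.028 in heart, -0.031 in fat and 0.041 in lung. Those of different numbers and groups did so by 0.014, -0.007, 0.016 and -0.02. The labels state no pairing by number, and such means cannot exclude one. With the number as a block the counts were 0 for the difference in liver and 6 for training in knockout hearts. They were 10 for the knockout in sedentary fat and 12 for training in vehicle lungs. edgeR on estimated reads gave 0 for the difference in liver.

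Without the libraries over the 10-fold limit for transcripts of another tissue, liver gave 1, 1, 10 and 0 (training in knockout mice, knockout in sedentary mice, knockout in trained mice, difference) and heart 0 and 500 (training in knockout mice, knockout in trained mice). With the 5-fold limit liver gave 0, 8 and 0 (training in knockout mice, knockout in trained mice, difference), and heart 521, 0, 4 and 1 (training in vehicle mice, training in knockout mice, knockout in sedentary mice, difference). With the sums as covariates liver gave 1, 219 and 0 (training in knockout mice, knockout in trained mice, difference), and heart 9, 6 and 224 (training in knockout mice, knockout in sedentary mice, knockout in trained mice). Without the 2 fat libraries over the 10-fold limit for hepatocyte transcripts other than Cyp2e1, also chosen after seeing the data, fat gave 3, 273, 1 and 1 (training in vehicle mice, knockout in sedentary mice, knockout in trained mice, difference). Without the 3 over the 5-fold limit it gave 0, 1 and 1 (knockout in sedentary mice, knockout in trained mice, difference). The 3 genes shared by both training comparisons in heart became 21 at an adjusted p under 0.1, 5 with a block, 0 without the libraries under either limit and 6 with covariates.

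Leaving out 1 library at a time gave these lowest and highest counts. In liver they were 0 to 8 for training in vehicle mice (highest without sedentary vehicle 5), 1 to 7 for training in knockout mice (highest without sedentary knockout 2), 0 to 0 for the knockout in sedentary mice, 4 to 595 for the knockout in trained mice (without trained vehicle 3 and trained vehicle 2) and 0 to 8 for the difference (highest without sedentary vehicle 5). In heart they were 418 to 1424 (without trained vehicle 1 and trained vehicle 5), 0 to 92 (highest without sedentary knockout 4), 0 to 3 (highest without sedentary vehicle 1), 4 to 270 (without trained vehicle 2 and trained knockout 5) and 0 to 0 in the same order. In fat they were 0 to 3 (highest without trained vehicle 2), 0 to 92 (highest without sedentary knockout 2), 0 to 199 (without sedentary vehicle 2 and sedentary knockout 1), 0 to 1630 (without trained vehicle 1 and trained knockout 1) and 0 to 472 (highest without trained knockout 1). In lung they were 0 to 206 for training in vehicle mice (without trained vehicle 1 and sedentary vehicle 1), 0 to 11 for the difference (highest without sedentary vehicle 1) and 0 to 0 otherwise. The genes shared by both training comparisons ranged from 0 to 1 in liver, 0 to 62 in heart (highest without sedentary knockout 4), 0 to 1 in fat and 0 to 0 in lung. Named genes kept their call in 738 such fits and lost it in 676.

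With an estimated correlation none of the 144 list calls passed, with adjusted p values of 0.963 and 0.994 in liver; 0.367, 0.715 and 0.751 in heart; 0.938 and 0.945 in fat; 0.858, 0.87 and 0.871 in lung. With fry, which tests whether the genes of a list move 1 way on balance, none passed either, with adjusted p values of 0.0565, 0.626, 0.662, 0.693, 0.76, 0.801, 0.815, 0.848, 0.861, 0.875, 0.884 and 0.938 in liver; 0.0914, 0.095, 0.181, 0.185, 0.193, 0.196, 0.224, 0.225, 0.274, 0.358, 0.362, 0.424, 0.486, 0.525, 0.541 and 0.629 in heart; 0.212, 0.217, 0.318, 0.327, 0.338, 0.361, 0.38, 0.432, 0.538, 0.582, 0.592, 0.637, 0.699, 0.71, 0.747 and 0.76 in fat; 0.265, 0.363, 0.509, 0.577, 0.584, 0.589, 0.605, 0.613, 0.618, 0.638, 0.669 and 0.708 in lung. With the replicate block the list calls lost had adjusted p values of 0.0574 in liver and 0.0533 and 0.0534 in lung. Without the libraries over the 10-fold limit they had 0.0506, 0.0798, 0.104, 0.109, 0.192, 0.248 and 0.815 in liver. On data simulated at the depth, spread and number of these libraries, 46 of 100 genes with a 1.5-fold change were recovered in liver, 67 in heart, 18 in fat and 20 in lung. What depth alone limits was tested in lung only, for training in vehicle mice, where 26 genes were called after thinning against 33 before.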

Other observations

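Other splits of the same libraries were fitted for every count, as planned before the results were seen. In liver, no other split reached the count of the knockout in trained mice (337 genes, highest other of 100 splits 11). That count still fell to 10 without the libraries that carried transcripts of another tissue. Chance is not excluded for training in knockout mice (3, highest other 10, with 5 of 100 splits reaching 3 or more) or the difference in training effect (1, highest other 5). In heart, no other split reached the count of training in vehicle mice (1113, highest other 363). Training in knockout mice (3, highest other 22, with 3 of 100 splits as large) and the knockout in trained mice (70, highest other 369, with 2 of 100 splits as large) had a share under 0.05. Chance is not excluded for these 2, as other splits called more genes and the shares were not adjusted over the comparisons. Where the real count was 0 every split reaches it, 100 of 100, so the splits say nothing about chance; the highest others were 37 and 604 in liver (training in vehicle mice, knockout in sedentary mice) and 2 and 173 in heart (knockout in sedentary mice, difference). Splits with 604, 369 and 173 calls, where the real split gave 0, 70 and 0, may reflect a structure of the samples other than the groups, which was not tested.

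For fat and lung, 10 splits of 6 libraries are too few for a share under 0.05. In fat the real and highest other counts were 0 and 0 for training in vehicle mice, 0 and 177 for training in knockout mice, 86 and 1 for the knockout in sedentary mice, and 685 and 0 for the knockout in trained mice. What lies behind the 177 calls was not tested. In lung they were 33 and 1 for training in vehicle mice and 0 and 0 for training in knockout mice, for the knockout in sedentary mice and for the knockout in trained mice. For the difference in training effect the real count was 0 in fat and in lung, which all 40 splits reach, so they say nothing about chance either (highest others 6 and 1).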
